A study of Homo sapiens with 4 samples.

How the data were processed

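Total RNA of A549 cells, 2 control and 2 sulforaphene samples taken at 24 h, was extracted with Trizol, converted to biotin-labelled cRNA with a 3' in vitro transcription kit and hybridised to 1 Affymetrix array per sample, per the labels' protocols. The deposited table gives 1 intensity per probe set and array, on a linear scale. RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a set) is named in the submitters' processing notes. Its version and settings are not given in the sources used here. RMA usually writes log2 values, but the deposited intensities ran from 2.59 to 14130 with medians near 26, so they were read as linear and log2-transformed, with no pseudocount. RMA's shared background correction compresses differences between dim probe sets, so fold changes of dim genes may be understated. All 4 columns belonged to the samples of this series.

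Of 54613 probe sets, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none there. Probe sets with several symbols or none were not used. Symbols were checked through the gene ID against RefSeq (GRCh38.p14), in which 41037 of the 41091 were found. The probe set with the highest mean log2 value over all arrays stood for each of 19775 genes. Genes whose probe set lay below the 40th percentile of all probe sets (a log2 value of 4.10, or 17.1 on the linear scale) were left out, which left 14029 genes.

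Sulforaphene was compared with control in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with an intensity trend on log2 values and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Errors given with ± are the standard errors of this model unless stated otherwise. The model had 2 residual and 3.15 prior degrees of freedom. The 21 gene lists hold 493 genes, with 0 genes on more than 1 list. Of these, 457 had a named probe set, 433 were tested and 36 were not analysed here. Lists were tested with camera at a preset correlation of 0.01, with camera's estimated correlation beside it, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Adjustment was over the 21 lists. At an estimated correlation 0 of the 5 list calls held.

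The genes named were fixed by rule. They were the 10 largest rises and the 10 largest falls among genes past the threshold with both treated arrays on the same side of both controls. In each list they were up to 3 members with the largest absolute log2 fold change that passed or, where none passed, the 1 member with the largest absolute log2 fold change, by its values only. HMOX1, NQO1, GCLM, DDIT3, ATF3, HSPA1A, CDKN1A, CCNB1 and MKI67 were named whatever their values. Lists, rule, tests and alternatives were set before the data were examined, except where stated.

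The alternatives were quantile normalization and median-centring of the arrays, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets whose names mark possible cross-hybridisation, eBayes without a trend and with a robust prior, the replicate number as a block, and leaving out each array. With 1 array left in a group, the fit assumes that it varies like the other group. A planned measure of RNA quality from the array's 3' and 5' control probe sets was not computed, because the table used here held 0 control probe sets.

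The procedure was tested on simulated arrays of the 14029 genes, 2 per group, in 20 runs with 200 changed genes each. It recovered 0.821% of genes changed 2-fold, 33.4% of those changed 4-fold and 77.0% of those changed 8-fold, with 3.85 false calls per run on average. Unchanged gene lists had a camera p under 0.05 in 2.62% of tests. The simulated genes were drawn independently of each other, so this share does not cover lists whose genes are correlated. For the same reason the count of false calls does not cover deviations that many genes of an array share. In the real data the estimated correlation was 0.20 for the mitosis list, 0.36 for heat shock and 0.41 for DNA replication. Figures were drawn with matplotlib 3.10.9.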

Results

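Gene expression was measured on 4 one-colour Affymetrix arrays of cells labelled A549, a human lung carcinoma cell line of epithelial origin. The identity of the cells rests on the labels. Transcripts known to be abundant in A549, such as AKR1B10 and, on its brightest probe set, KRT7, were bright on only 1 of the 4 arrays. CDKN2A, of a locus known to be lost in A549, had signal on all 4 arrays with 2 of its 3 probe sets. Cells received sterile water as control (2 arrays) or 30 µmol/L sulforaphene (2 arrays) for 24 h. Sulforaphene is an isothiocyanate of radish, an electrophilic compound related to the sulforaphane of broccoli. The deposited table held 54613 probe-set intensities per array on a linear scale. Median intensity was 26.04 on control replicate 1, 26.73 on control replicate 2, 26.89 on sulforaphene replicate 1 and 26.39 on sulforaphene replicate 2. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

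The control arrays differed from each other in a defined set of genes. On control replicate 2, 122 of the 14029 genes tested were more than 8-fold higher than on control replicate 1, and 0 were more than 8-fold lower. Between the sulforaphene arrays, 0 genes were more than 8-fold higher on replicate 2 than on replicate 1, and 4 were more than 8-fold lower. The aldo-keto reductase AKR1B10, which reduces reactive aldehydes, had an intensity of 9669 on control replicate 2, against 85.2 on control replicate 1, 143 on sulforaphene replicate 1 and 28.4 on sulforaphene replicate 2. The secreted disulfide isomerase family member AGR2 stood at 3288 there and at 10.4, 12.5 and 15.3 on the same other arrays. Simple-epithelium keratin KRT7 stood at 2366 on control replicate 2 and at 18.4, 26.3 and 13.1 on the others, on its brightest probe set. There its log2 fold change for sulforaphene was −3.49, against −1.03 with the mean of its probe sets and 0.13 without those that can cross-hybridise. The excess of KRT7 on control replicate 2 may therefore not hold on its other probe sets. KRT8, another keratin of simple epithelia, stood at 1701 against 39.5, 72.4 and 59.0. AGR2, KRT8 and CDKN2A were picked here after their values were seen. The spread between the controls kept these genes out of reach of the test for sulforaphene. In all, 93.5% of the genes tested lay within 2-fold of each other on both control arrays.

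**Figure D1:**
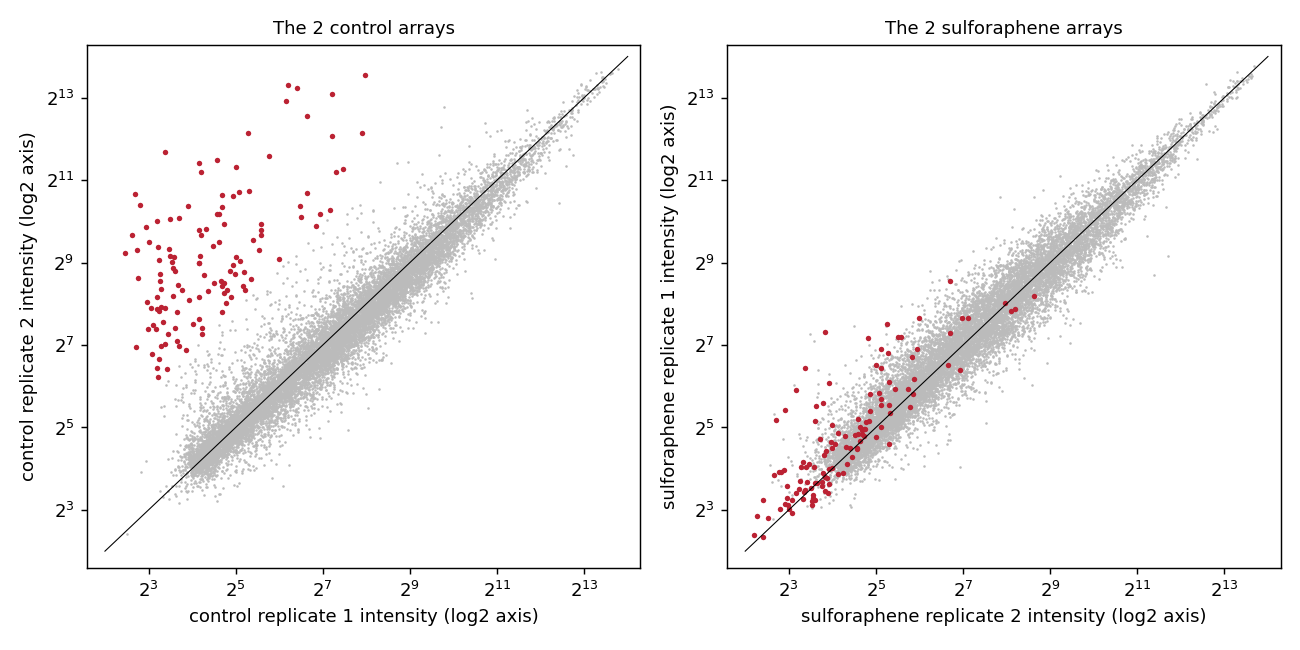
Probe-set intensity of each gene tested on one replicate against the other (both axes log2), for the control arrays on the left and the sulforaphene arrays on the right. Red points are the 122 genes more than 8-fold higher on control replicate 2 than on control replicate 1, grey points the other genes, and the line marks equal intensity.

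The comparison of sulforaphene with control asks which genes differ in expression in these cells after 24 h of treatment. FOSB, a subunit of the AP-1 transcription factor, rose 19.6-fold (log2 fold change 4.29 ± 0.43 SE, n = 2 arrays per group, limma adjusted p = 0.0475). TNFRSF10D, a decoy receptor for the death ligand TRAIL, rose 14.7-fold (3.87 ± 0.27, limma adjusted p = 0.0475), and the creatine transporter gene SLC6A8 rose 13.1-fold (3.71 ± 0.34). The largest falls, on the brightest probe set of each gene, were those of RAB27B, a small GTPase of vesicle secretion, whose log2 fold change was −4.11 ± 0.55, and of MALL, a membrane raft protein of the MAL family, at −3.45 ± 0.42. KIF11, the kinesin that drives apart the poles of the mitotic spindle, fell by 3.34 on the log2 scale (SE 0.34).

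The other genes among the 10 largest rises were LINC00324, KLHL24, OSER1-DT, ZNF684, RSRP1, RRN3P2 and MXD1, with log2 fold changes from 3.59 for the long noncoding RNA LINC00324 to 3.00 for MXD1, an antagonist of MYC at shared binding sites. RSRP1 went from 401 and 352 on the control arrays to 2792 and 3687 after sulforaphene. The remaining largest falls were those of PPP1R9A, NIPSNAP3A, RHNO1, BRI3BP, MATN2, EIF2AK2 and CDCA7, from −3.38 for the actin-binding PPP1R9A to −2.81 for CDCA7, a gene of proliferating cells. EIF2AK2, the kinase activated by double-stranded RNA, had a log2 fold change of −2.82 ± 0.32. The probe sets of SLC6A8, RSRP1, NIPSNAP3A, MATN2 and CDCA7 are of a type that can cross-hybridise, and RRN3P2 is a pseudogene. All these values may therefore include signal of related sequences. With the mean of all a gene's probe sets, the log2 fold change was nearer to 0 by over 1.5 times for KLHL24 (1.88), OSER1-DT (1.71), RAB27B (−2.02), PPP1R9A (−2.06), MATN2 (−1.47) and EIF2AK2 (−1.42), and the same held for SLC6A8 (2.31) and CDCA7 (−1.36) without probe sets that can cross-hybridise. Under these settings RAB27B, PPP1R9A and MATN2 stayed past the threshold, and the calls ended for KLHL24 (limma adjusted p = 0.0520), OSER1-DT (0.0610), EIF2AK2 (0.0546), SLC6A8 (0.0521) and CDCA7 (0.116). The control intensities of OSER1-DT and RRN3P2 and the treated ones of NIPSNAP3A lay below 17.1, where probe sets were treated as dim, so the sizes of these differences are uncertain.

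Of 14029 genes, 247 passed the limma test at an adjusted p under 0.05, 118 with higher and 129 with lower expression after sulforaphene. All 247 changed at least 2-fold and had both treated arrays on the same side of both control arrays. The adjusted p-values of these genes lay between 0.0475 and 0.0499, and 1753 genes (761 higher, 992 lower) had an adjusted p under 0.10. Groups that did not overlap were found for 7999 genes (57.0%), where 33.3% is the chance for a single gene. Genes on the same arrays share array effects, so this excess does not test the treatment. The count rested on each array: limma gave 139 genes (12 rose, 127 fell, 20 of them among the 247) without control replicate 1, 0 without control replicate 2, 0 without sulforaphene replicate 1 and 0 without sulforaphene replicate 2. The last 3 comparisons had 2525, 2865 and 2360 genes at an unadjusted p under 0.05, against 3676 on all arrays. Without a filter on dim probe sets 0 genes passed, with 3981 at an unadjusted p under 0.05. All 35 named genes that passed kept their direction when any array was left out. Their naming rule, with both treated arrays on the same side of both controls, allowed no other outcome.

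**Figure D2:**
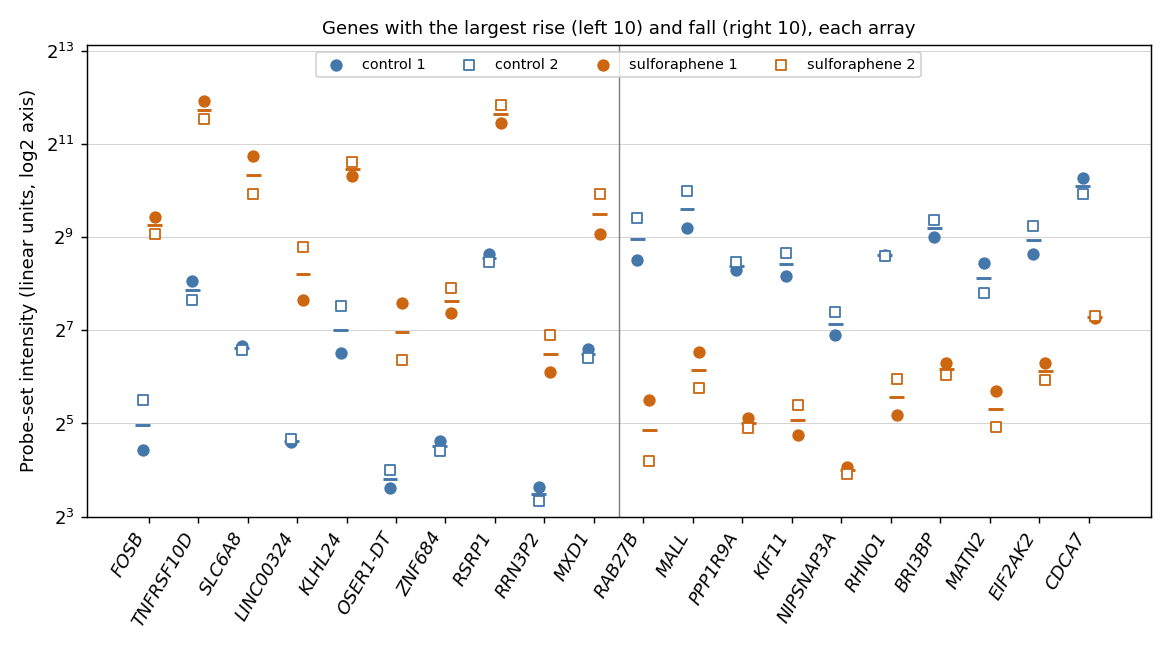
Probe-set intensity on each array (log2 axis) of the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold. Points are single arrays and short bars the group means of the log2 values; both sulforaphene arrays lie on the same side of both control arrays for each gene, as for FOSB, at 21.4 and 45.5 in control and 696 and 538 after sulforaphene.

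Genes of cell division were lower after sulforaphene. Of 36 mitosis genes, 3 fell, 0 rose and 33 did not pass the test over all genes; adjusted over the list alone, 20 fell and 0 rose. The 3 were KIF11, the spindle and centrosome protein gene ASPM at −1.89 ± 0.25 and the checkpoint kinase gene BUB1B at −1.60 ± 0.23. The list's median log2 fold change was −0.90, with 33 members below 0 (camera adjusted p = 2.7e-07; adjusted p = 0.650 with an estimated correlation). CCNB1, cyclin B1, had −1.08 ± 0.33 (limma adjusted p = 0.123), and the proliferation marker MKI67 −0.21 ± 0.30 (limma adjusted p = 0.707). Both depended on the probe sets used: with the mean of a gene's probe sets CCNB1 had −2.24 and MKI67 −1.26, and without probe sets marked as possibly cross-hybridising CCNB1 had −3.39; MKI67 had 0.09 without control replicate 1. The count adjusted over the list alone rested on each array: 1 fell without control replicate 1, 1 without control replicate 2, 2 without sulforaphene replicate 1 and 8 without sulforaphene replicate 2. Without control replicate 2 the list's median was −0.77.

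DNA replication genes moved the same way. Of 41 members, 1 fell, 0 rose and 40 did not pass; adjusted over the list alone, 14 fell and 1 rose. LIG1, the DNA ligase that joins lagging-strand fragments, fell by 2.01 on the log2 scale (SE 0.25, limma adjusted p = 0.0475), from 366 and 312 on the control arrays to 84.7 and 83.0. The median over the list was −0.77, with 36 members below 0 (camera adjusted p = 1.0e-06; adjusted p = 0.666 with an estimated correlation). Adjusted over the list alone, 0 members fell without control replicate 1, 8 without control replicate 2, 11 without sulforaphene replicate 1 and 0 without sulforaphene replicate 2. Without control replicate 2 the median was −1.03.

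Autophagy and lysosome genes were higher. Of 20 members, 3 rose, 0 fell and 17 did not pass; adjusted over the list alone, 10 rose and 0 fell. MAP1LC3B, whose product is lipidated on autophagosome membranes, rose 4.08-fold (log2 fold change 2.03 ± 0.17, limma adjusted p = 0.0475), from 1558 and 1223 to 5622 and 5637. ATP6V0D1, a subunit of the proton pump that acidifies lysosomes, rose 3.34-fold, and GABARAPL2, an LC3-related autophagy gene, rose 2.16-fold. The probe sets of MAP1LC3B and GABARAPL2 are of a type that can cross-hybridise, and neither gene had a value without such probe sets. The list's median was 0.77, with 17 members above 0 (camera adjusted p = 1.2e-05; adjusted p = 0.650 with an estimated correlation). Without control replicate 2 it was 0.65, and 5 members rose adjusted over the list alone.

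Heat shock genes were higher as a list, with a median of 0.70 over 18 members and 14 above 0 (camera adjusted p = 0.0033; adjusted p = 0.666 with an estimated correlation). The small heat shock protein gene HSPB8 rose 4.95-fold (2.31 ± 0.26, limma adjusted p = 0.0475), 0 members fell and 17 did not pass; adjusted over the list alone, 6 rose and 0 fell. HSPA1A was not analysed here. HSPB8 had 1.00 (limma adjusted p = 0.103) without probe sets that can cross-hybridise. Adjusted over the list alone, 1 member rose without control replicate 2, 0 without sulforaphene replicate 1 and 0 without sulforaphene replicate 2. Without control replicate 2 the median was 0.51 (camera adjusted p = 0.028; adjusted p = 0.617 with an estimated correlation).

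Cholesterol biosynthesis genes were lower as a list, although 0 of 18 members passed the test over all genes; adjusted over the list alone, 3 fell and 0 rose. The median was −0.45, with 14 members below 0 (camera adjusted p = 0.047; adjusted p = 0.650 with an estimated correlation). FDPS, the farnesyl diphosphate synthase gene, had the largest difference, −1.36 ± 0.32 (limma adjusted p = 0.0830). The call was lost without control replicate 2 (camera adjusted p = 0.114) and without sulforaphene replicate 1 (0.209). Adjusted over the list alone, 0 members fell when any array was left out.

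NRF2 target genes, which electrophiles induce through the sensor KEAP1, gave opposite directions against the 2 control arrays. With all arrays, 0 of 26 members rose or fell, also adjusted over the list alone. The median was −0.49 (camera adjusted p = 0.708; adjusted p = 0.980 with an estimated correlation), with 11 members above 0 and 15 below. Against control replicate 1 alone the median was 0.46, with 17 members above 0. Against control replicate 2 alone the median was −1.33. The list's members were higher on control replicate 2 than on control replicate 1 by a median of 1.88.

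NQO1, a quinone reductase and a standard NRF2 target, had 839 on control replicate 1, 4984 on control replicate 2, and 1888 and 2457 after sulforaphene, a log2 fold change of 0.07 ± 0.82 (limma adjusted p = 0.966). It was 1.36 without control replicate 2 and −1.21 without control replicate 1. GCLM, a subunit of the enzyme that makes the first step of glutathione synthesis, had higher intensity on both sulforaphene arrays, at 2566 and 2322, than on the control arrays, at 915 and 1395 (1.11 ± 0.26, limma adjusted p = 0.0796). The heme oxygenase gene HMOX1 had 0.39 ± 0.53 (limma adjusted p = 0.690), and −0.34 without control replicate 2. AKR1B10 had the largest difference on the list, −3.83 ± 2.26 (limma adjusted p = 0.356), and −0.42 without control replicate 2. Probe sets of the AKR1C genes can share signal among these close paralogs.

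**Figure D3:**
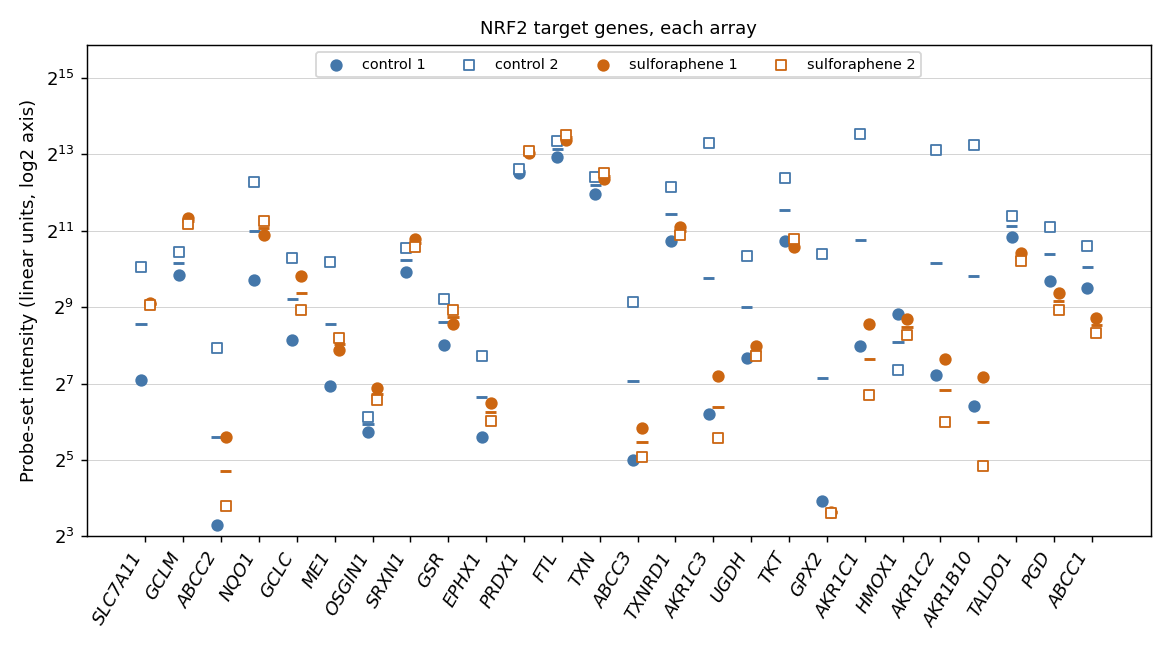
Probe-set intensity on each array (log2 axis) of the 26 NRF2 target genes tested, ordered by their log2 fold change without control replicate 2. Points are single arrays and short bars the group means of the log2 values; NQO1 lay at 1888 and 2457 after sulforaphene, above control replicate 1 at 839 and below control replicate 2 at 4984.

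Single stress genes rose in other lists that did not pass as a whole. In the ATF4 and amino acid response list (27 members, median 0.23, camera adjusted p = 0.0774), PPP1R15A, the phosphatase subunit that reverses eIF2-alpha phosphorylation, rose 4.55-fold (2.19 ± 0.22, limma adjusted p = 0.0475) and 26 members did not pass; adjusted over the list alone, 2 rose and 0 fell. ATF3 had 44.7 and 153 in control and 1312 and 895 after sulforaphene (3.71 ± 0.63, limma adjusted p = 0.0565), and DDIT3, which encodes CHOP, 1.71 ± 1.01 (limma adjusted p = 0.359), with 0.36 without sulforaphene replicate 2 and 3.05 without sulforaphene replicate 1. The list's median was 0.33 without control replicate 2 (camera adjusted p = 5.3e-05; adjusted p = 0.617 with an estimated correlation) and 0.07 without control replicate 1 (camera adjusted p = 0.939); without sulforaphene replicate 1 its camera adjusted p was 0.0238, against 0.860 with all arrays and an estimated correlation.

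Among 21 immediate early and MAPK feedback genes (median 0.64, camera adjusted p = 0.0660), FOSB rose and 20 did not pass; adjusted over the list alone, 2 rose and 0 fell. That list passed without control replicate 1 (camera adjusted p = 0.0467) and without sulforaphene replicate 1 (0.0036), and with the mean of probe sets (0.0435); with all arrays and an estimated correlation its adjusted p was 0.666. Among 21 apoptosis regulators (median 0.11, camera adjusted p = 0.129), PMAIP1, which encodes the BH3-only protein NOXA, rose 4.61-fold (2.21 ± 0.31, limma adjusted p = 0.0496) and 20 did not pass; adjusted over the list alone, 1 rose and 0 fell.

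The p53 targets went both ways. GADD45A, a growth arrest gene, rose 2.77-fold (1.47 ± 0.13, limma adjusted p = 0.0475), the DNA repair gene DDB2 fell by 2.15 on the log2 scale (SE 0.28), and 18 of 20 did not pass; adjusted over the list alone, 5 rose and 4 fell. The list's median was −0.09 and its mean −0.05, while camera's direction was up (adjusted p = 0.708). The cell cycle inhibitor CDKN1A had 533 and 521 in control and 1307 and 1284 after sulforaphene (1.30 ± 0.21, limma adjusted p = 0.0559).

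In the list of receptor tyrosine kinases and PI3K-AKT components, 1 of 23 members passed (median −0.33, camera adjusted p = 0.0660), and adjusted over the list alone 1 rose and 0 fell. It was GSK3B, a kinase that AKT inhibits, which rose 3.89-fold on its brightest probe set (1.96 ± 0.24, limma adjusted p = 0.0475). Its probe sets disagreed, with log2 fold changes of 1.96, −1.98, −1.76, 0.14 and −0.23, and the mean over them was −0.38. The list passed without control replicate 1 (camera adjusted p = 0.0467), without sulforaphene replicate 1 (0.0238) and without a filter on dim probe sets (0.0199); with all arrays and an estimated correlation its adjusted p was 0.650.

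The glucose transporter gene SLC2A3 rose 3.45-fold (1.79 ± 0.26, limma adjusted p = 0.0496) among 23 hypoxia and glycolysis genes, of which 22 did not pass and, adjusted over the list alone, 3 rose and 4 fell (median −0.15, camera adjusted p = 0.962). The zinc importer gene SLC39A10 fell by 2.11 (SE 0.25) among 9 metallothionein and metal response genes, of which 8 did not pass and 1 fell when adjusted over the list alone (median −0.44, camera adjusted p = 0.190, and 0.0026 without sulforaphene replicate 1; adjusted p = 0.860 with all arrays and an estimated correlation). VIM, the intermediate filament gene of mesenchymal cells, fell by 1.32 (SE 0.15, limma adjusted p = 0.0475), from 10053 and 8692 to 4143 and 3382. It was the only call among 14 mesenchymal markers, of which 3 rose and 1 fell adjusted over the list alone (median −0.19, camera adjusted p = 0.985).

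Epithelial markers followed control replicate 2. None of 14 passed, also adjusted over the list alone (median −1.05, camera adjusted p = 0.135), where 9 fell without control replicate 1 and 0 without each other array, and the members were higher on control replicate 2 than on control replicate 1 by a median of 1.22. KRT7 had −3.49 ± 2.22 (limma adjusted p = 0.387) and 0.014 without control replicate 2, where the list's median was 0.01; without control replicate 1 the median was −1.91 (camera adjusted p = 2.3e-05; adjusted p = 0.860 with all arrays and an estimated correlation). The list of NF-kB and inflammatory genes had 0 of 19 calls, also adjusted over the list alone (median −0.60, camera adjusted p = 0.135, and 0.0011 without control replicate 1; adjusted p = 0.650 with all arrays and an estimated correlation). Its largest difference was −3.85 ± 2.20 for the chemokine gene CXCL5 (limma adjusted p = 0.342), and −0.32 without control replicate 2. CXCL5 stood at 6.15 and 815 on the control arrays and at 5.25 and 4.60 on the treated ones. All but the 815 lay below 17.1, where probe sets were treated as dim, so the sizes of these differences are uncertain.

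No member passed in 5 further lists. Proteasome subunits (27 members) had a median of 0.13 (camera adjusted p = 0.148, and 0.0427 without control replicate 1; adjusted p = 0.860 with all arrays and an estimated correlation), led by PSMD12 at 0.85 ± 0.21, which turned to −0.24 with the mean of its probe sets. Endoplasmic reticulum chaperones and unfolded protein response genes (19) had a median of 0.11 (camera adjusted p = 0.661), led by the cochaperone gene DNAJB9 at 1.94 ± 0.59 (1.15 without sulforaphene replicate 2). Tubulins (13) had a median of −0.14 (camera adjusted p = 0.708), led by TUBA4A at −1.11 ± 0.90, which turned to 0.28 without control replicate 2. Interferon-stimulated genes (16) had a median of 0.02 (camera adjusted p = 0.977), led by the transcription factor gene IRF7 at 1.42 ± 0.29; adjusted over the list alone, 2 rose and 1 fell, which became 3 and 2 without control replicate 1 and 0 and 0 without each other array. Markers of cell types other than epithelium (8) had a median of 0.13 (camera adjusted p = 0.302), led by CD14 at 1.93 ± 0.75 (0.85 without sulforaphene replicate 1). In the other 4 of these lists 0 members rose or fell adjusted over the list alone.

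**Figure D4:**
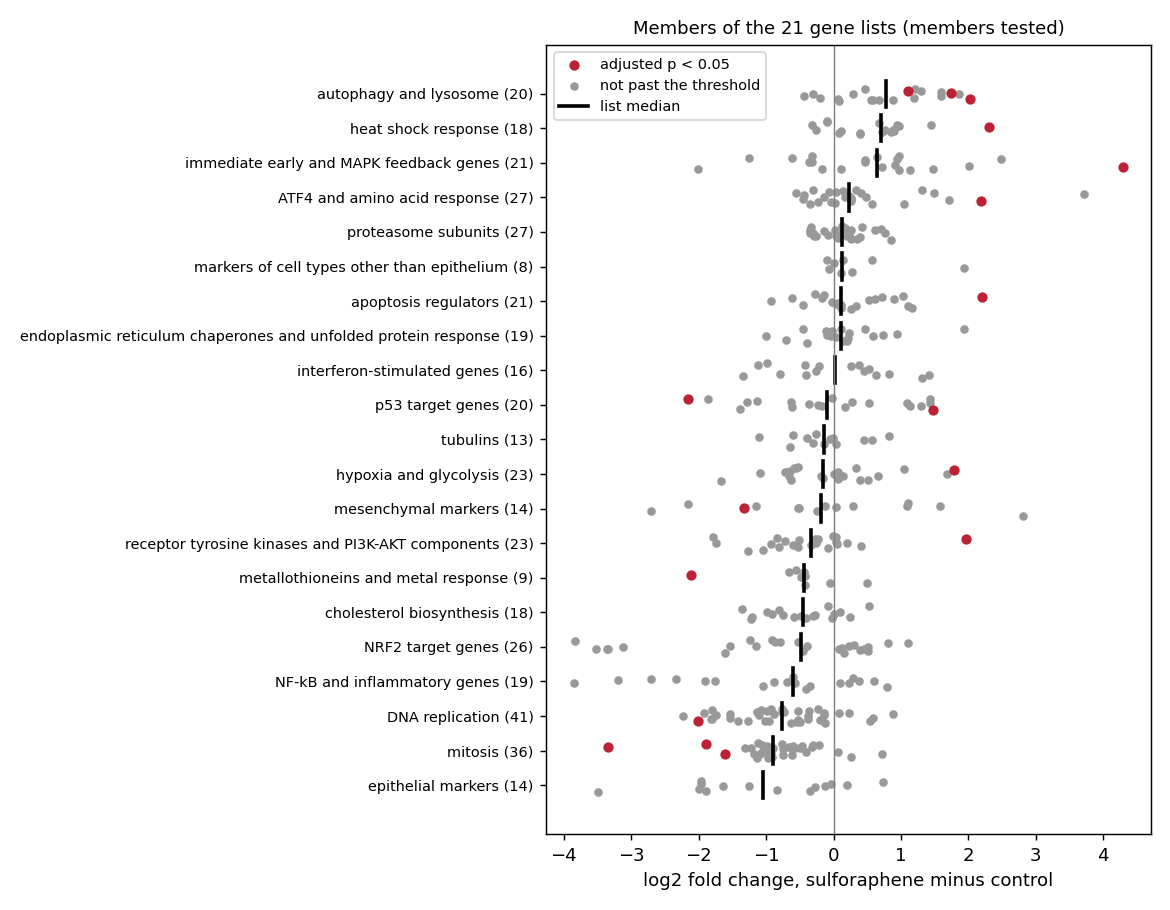
Log2 fold change (sulforaphene minus control) of each tested member of the 21 gene lists, ordered by list median. Red points passed an adjusted p under 0.05, grey points did not, and black bars are list medians, from −1.05 for epithelial markers to 0.77 for autophagy and lysosome genes.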

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

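The count of 247 genes (118 up, 129 down) became 298 with quantile normalization and 300 with median-centring. It was 0 without a filter (3981 genes at an unadjusted limma p under 0.05), 965 with the filter at the 60th percentile (422 up, 543 down; 940 at least 2-fold) and 1265 with every probe set on its own (544 up, 721 down; 1260 at least 2-fold). It was 140 without an intensity trend (67 up, 73 down) and 400 with a robust prior, 223 of them down. Leaving out single arrays gave 0 to 139 genes, 0 to 12 up and 0 to 127 down, all at least 2-fold. More or fewer genes tested change the adjustment, and fewer arrays lower the degrees of freedom; other causes were not tested. The adjusted p-values of the calls lie close to the threshold, so small shifts of the whole list decide the count. Of the 35 named genes that passed, all kept their direction when any array was left out, and 7, 0, 0 and 0 stayed past the threshold without control replicate 1, control replicate 2, sulforaphene replicate 1 and sulforaphene replicate 2. The directions of these named genes could not have changed, because naming required both treated arrays on the same side of both controls. Dim signal limits genes near the background, and the 2 arrays per group limit the rest.

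The replicate number was shared by a control and a sulforaphene array, but same-numbered arrays did not deviate together (correlation of their deviations 0.04 across genes), so nothing shows that they were pairs. The correlation includes the 122 genes far higher on control replicate 2, of which 91 were higher on sulforaphene replicate 1 than 2. These genes lower it, so it cannot exclude pairs. With the replicate block, 0 genes passed and 3787 had an unadjusted p under 0.05.

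The number of lists past the threshold, 5 with all arrays, was 5 to 11 without single arrays, and 0 with an estimated correlation and 0 with fry. Adjusted p with an estimated correlation was 0.666 for heat shock and DNA replication and 0.650 for mitosis, autophagy and lysosome, and cholesterol biosynthesis; with fry it was 0.283, 0.214, 0.185, 0.148 and 0.214 in the same order. For cholesterol biosynthesis, camera gave 0.0566 with quantile normalization and 0.0781 with the filter at the 60th percentile and with the mean of probe sets, and 0.0028 to 0.209 without single arrays. The directions of all 5 lists held under both scalings. Of lists that did not pass, 1 passed without a filter (receptor tyrosine kinases and PI3K-AKT components, 0.0199) and 1 with the mean of probe sets (immediate early genes, 0.0435); with an estimated correlation their adjusted p was 0.650 and 0.666. Without single arrays, counts adjusted over the list alone ranged from 0 to 5 up and 0 to 4 down for p53 targets, 0 to 4 up and 0 to 3 down for hypoxia genes, 1 to 6 up and 0 to 1 down for immediate early genes, 0 to 3 up and 0 to 2 down for interferon-stimulated genes, 1 to 3 up and 1 to 3 down for mesenchymal markers, 0 to 3 up for ATF4 genes, 0 to 1 up and 0 to 2 down for receptor tyrosine kinases and PI3K-AKT components, 0 to 1 up and 0 to 2 down for tubulins, 0 to 1 up for markers of cell types other than epithelium, 0 to 9 down for epithelial markers, 0 to 6 down for NF-kB genes and 1 to 7 down for metallothioneins.

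Directions reversed for lists that did not pass, with causes not tested. Without single arrays, camera adjusted p ranged from 2.0e-05 to 0.922 for NRF2 targets, 0.145 to 0.922 for endoplasmic reticulum genes, 0.184 to 0.922 for p53 targets, 0.289 to 0.994 for tubulins, 0.782 to 0.922 for interferon-stimulated and for hypoxia genes, 0.0026 to 0.922 for metallothioneins, 2.3e-05 to 0.829 for epithelial markers and 0.782 to 0.925 for mesenchymal markers. Interferon-stimulated genes also reversed without a filter (0.691), with the mean of probe sets (1.00) and with the replicate block (0.871). Hypoxia genes reversed with the filter at the 60th percentile (0.923) and with fry (0.891). Mesenchymal markers reversed with quantile normalization (0.988), the filter at the 60th percentile (0.923), the mean of probe sets (0.866) and fry (0.891).

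Among named genes, log2 fold changes without single arrays ranged from −2.49 to 0.28 for TUBA4A, −7.00 to 0.014 for KRT7, −0.34 to 1.13 for HMOX1, −1.21 to 1.36 for NQO1, −0.51 to 0.087 for MKI67, 0.36 to 3.05 for DDIT3, 0.85 to 3.02 for CD14, −7.37 to −0.32 for CXCL5 and −7.24 to −0.42 for AKR1B10. Without sulforaphene replicate 2, DNAJB9 had 1.15, and without sulforaphene replicate 1, CCNB1 had −0.64. With the mean of probe sets they were −0.24 for PSMD12, −0.38 for GSK3B, −0.28 for NQO1, −1.26 for MKI67, −2.24 for CCNB1, −1.03 for KRT7, 0.65 for GCLM and 2.33 for ATF3. Without probe sets marked as possibly cross-hybridising they were −1.76 for GSK3B, 0.13 for KRT7 and −3.39 for CCNB1, because another probe set then stood for the gene. Of the 35 named genes that passed, 27 had a value under this setting and 22 stayed past the threshold. RSRP1, NIPSNAP3A, MATN2, MAP1LC3B, GABARAPL2, PMAIP1, SLC2A3 and VIM had no value there.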

Other observations

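The gene families below, the tests of scaling, of a different culture, of a share on sulforaphene replicate 1 and of the CDKN2A and MTAP locus, and the KRT18 values were chosen after the data had been seen. Histone genes had higher signal after sulforaphene. Of 42 tested, 37 had a higher mean and 4 rose (H3C1, H2BC9, H3C2 and H2AC17), among them H2BC9 at 4.19-fold (log2 fold change 2.07 ± 0.25 SE, limma adjusted p = 0.0475) and H2AC17 at 3.59-fold. H3C1 was dim on the control arrays, at 12.3 and 11.9, so the size of its difference is uncertain. The median of the histone genes was 0.70, above the upper limit of 0.16 of the central 95% of 10000 random gene sets matched on mean level. Probe sets of near-identical histone genes can share signal, so single members are uncertain. The labelling used a 3' in vitro transcription kit, and whether this signal follows total histone mRNA was not tested. V-ATPase subunits, which acidify lysosomes, had a median of 0.79 over 20 genes, 17 of them higher. Of these, 3 rose, namely ATP6V0D1 (also on the autophagy and lysosome list), ATP6V1E1 at 2.82-fold and ATP6V1G1 at 2.18-fold. Genes named ZNF, mostly zinc finger transcription factors, had a median of 0.33 over 376 genes, with 22 that rose and 3 that fell. ZNF684 rose 8.66-fold and ZNF622 5.79-fold. Genes of ribosomal proteins (56) had a median of 0.05, inside the range of random sets. With an estimated correlation the camera p of the first 3 families was 0.0661, 0.0561 and 0.138, so none held there. The directions were the same under quantile normalization and median-centring.

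Without control replicate 2, whose profile differed from the rest, all 3 families stayed above the upper limit of matched random sets, with medians of 0.83, 0.75 and 0.23. No biological explanation of them was tested beyond the treatment, which remains open.

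The 122 genes more than 8-fold higher on control replicate 2 than on control replicate 1 differed by a median of 4.57 (log2). Of these, 115 were more than 4-fold higher on control replicate 2 than on each other array. An overall difference in scaling or background left in the deposited values is argued against by the 93.5% of genes within 2-fold on both controls. A difference that RMA had already removed would not show in that share. A wholly different culture stays open: 0 genes were more than 8-fold lower on control replicate 2, but this count was part of the first look. How many genes a different culture would lower was assumed. At a cutoff of 4-fold, 219 genes were higher and 14 lower on control replicate 2 than on control replicate 1. Added RNA with high NRF2 target expression is a candidate explanation. The 21 NRF2 list members held out from the first look were higher on control replicate 2 by a median of 1.41 (quartiles 0.56 and 2.57). Of them, 20 lay above 0, and HMOX1 was lower, at 454 on control replicate 1 and 163 on control replicate 2. Whether added RNA could give the 14 genes more than 4-fold lower was not tested. Of these 21, ABCC2, ABCC3 and ME1 also belong to the 122 genes, so the held-out members are not wholly separate from the pattern. Whether a small share of the same RNA is on sulforaphene replicate 1 is not settled. The 122 genes were higher there than on sulforaphene replicate 2 by a median of 0.27. The upper limit of the central 95% of matched random sets was 0.096, but only 91 of the 122 were higher. Of the 35 genes above 1000 on control replicate 2, 28 were higher on sulforaphene replicate 1, among them AKR1B10 at 143 against 28.4. The other 7 were lower, among them AGR2 at 12.5 and 15.3. Both AGR2 values lay below 17.1, where probe sets were treated as dim, so AGR2 cannot decide the question. Whether the signal on control replicate 2 came from other cells or from another state of that culture stays open, since no group of the design separates that array, and no biological explanation was tested.

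The reverse reading is that control replicate 2 is the array with A549 transcripts and that the cells on the other 3 arrays may not be typical A549. A549 is known for a mutation of KEAP1 with constitutively high NRF2 target expression and for a homozygous loss of the locus of CDKN2A and its neighbour MTAP. The median percentile of their 9 probe sets among all probe sets was 69.4 on the other 3 arrays and 70.4 on control replicate 2, so this median does not separate the arrays and leaves the reading open; the comparison with control replicate 2 was added after its value had been seen. Ranking different probe sets by level is also weak evidence of expression. For CDKN2A, intensities on control replicates 1 and 2 and sulforaphene replicates 1 and 2 were 113, 96.6, 147 and 119 on one probe set, 398, 327, 373 and 300.5 on another, of a type that can cross-hybridise, and 21.04, 17.2, 19.4 and 17.2 on the last, near the dim limit of 17.1. Of the MTAP probe sets, 4 were higher on control replicate 1 than on control replicate 2, but on 3 of these control replicate 2 was not below both sulforaphene arrays: in the same order they stood at 252, 101, 106 and 61.3, at 193, 78.6, 115 and 85.1, at 130, 80.7, 73.1 and 40.3, and at 78.5, 40.02, 40.25 and 32.3. A mixed or misidentified culture therefore stays open, as does cross-hybridisation, since no reference profile of A549 was used here, and every treatment value above applies to the cells as labelled. KRT18 stood at 880, 6952, 1548 and 689 on the same arrays.

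The lower mitosis and DNA replication genes could in principle reflect the same array. Their joint median over 77 genes was −0.88 with all arrays and −0.81 without control replicate 2, a ratio of 0.922, which argues against that array as the source. The treatment, or a difference in growth between the cultures, remains open.

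The kinase gene GSK3B had probe sets that differed in opposite directions by similar amounts. The brightest stood at 156 and 153 on the control arrays and at 615 and 584 after sulforaphene, while another went from 302 and 393 to 115 and 89.6 and one more from 81.0 and 99.2 to 24.4 and 21.04.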
